A study of Mus musculus with 4 samples.

How the data were processed

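RNA was sequenced from mouse primary cells labelled T-helper 17 (Th17), of strain C57BL/6NJ, in 4 libraries that the labels number as biological replicates 1 to 4. Th17 cells are CD4 T cells that make interleukin 17. The labels put all 4 libraries in 1 group, give each library a biosample record of its own and share 1 donor record among them, and give no control group, age or sex. They link to a protocol for the differentiation of CD4 T cells. They call the assay total RNA-seq, whereas the linked library protocol is titled as a poly(A)+ method.

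The deposited values are raw fragment counts per gene, 1 library per file. Per the file headers, counts were made with featureCounts 1.4.6-p4 on exons of GENCODE M13 (mm10), with fragments counted in pairs, both ends required to map, and the reverse-strand setting. No option for multi-mapping or multi-gene fragments appears on the command line in the file headers, so fragments shared between near-identical copies, such as Hspa1a and Hspa1b or many ribosomal protein genes and their pseudogenes, were left out and such genes are undercounted by an unknown amount. The aligner's version is not given in the sources used here. The alignment names in the file headers carry an hour tag of 0 for every library, and their replicate numbers match the labels. Text listings of files were not used.

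Each table held 50600 gene rows. Gene symbols came from GENCODE M21 by gene ID without its version, which matched 50376 IDs and left 224 without a symbol. Those 224 held 0.0141% ± 0.000902 of counts (SD, n = 4) and stayed in the totals, since each names a gene. Of 663 symbols in the gene lists, 2 were matched through a RefSeq synonym and the others directly. Coordinates are those of the deposited tables, 1-based, mm10. Total counts were 29041979, 35018552, 48808978 and 45490373 in replicates 1 to 4. TPM, transcript abundance scaled by gene length to a fixed library total, was computed here from the deposited counts and the union exon length in the same tables. Effective lengths and posterior estimates had been foreseen when the tests were fixed and were not used here, because the values are whole counts. A count of 0 allowed up to 3 counts, and limits of this kind cover counting error only.

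The tests, the 39 gene lists and the rule for named genes were fixed before the data were examined. Named genes were a fixed panel of lineage genes, the 10 nuclear protein-coding genes of highest mean TPM, the 15 excess variable genes of smallest adjusted p, up to 4 members of each list by mean TPM (2 for lists of other cell types), up to 4 members by p of each list past a spread or enrichment test, and the sex chromosome genes at 1 TPM or more in any library. Some genes that the rule takes are not reported here. Genes outside the rule are named as chosen after their values were seen. The Th17 list was compared with each of 14 other lists by a two-sided permutation test across genes with 100000 resamples of the difference in mean log2(TPM + 1), averaged over libraries, with genes in both lists left out. Genes are not independent replicates, so these p-values describe the lists in these libraries. The 12 gene pairs, of which 7 are covered here, were compared by an exact two-sided sign-flip permutation test of the 4 log2 ratios with a pseudocount of 0.1, whose smallest possible p is 0.125. Benjamini-Hochberg adjustment was applied within each family.

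Spread between replicates was measured with edgeR 4.0.16 in R 4.3.3 with an intercept-only design, TMM factors and filterByExpr, which kept 12464 genes at its count minimum in all 4 libraries. The biological coefficient of variation is the square root of the common dispersion. A gene was called excess variable when its quasi-dispersion exceeded the prior trend in a one-sided F test with an adjusted p below 0.05. On simulated counts for these 12464 genes with 1 library changed, the test recovered 6% of genes changed 2-fold and 70% of genes changed 4-fold, with 3 false calls among 79, and it made 0 calls where nothing had been changed. The simulated genes varied independently, with dispersions drawn from the fitted prior that the test assumes. The few false calls there therefore do not show the error rate in the real counts. List spread was the SD over the 4 libraries of the list's mean centred log2(CPM + 1), set against 10000 random lists matched on expression decile, one-sided, for the 30 lists with 5 or more genes past the filter. Enrichment of these lists among excess variable genes used a one-sided Fisher's exact test against all genes tested. Both list tests take genes as independent, so a list whose genes vary together can pass through a shift in 1 library. Their p-values describe these 4 libraries. DESeq2 1.42.0 gave an alternative. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the other steps, and list tests were tested on simulated data.

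Alternatives covered pseudocounts, filters, normalization, length correction, medians, thinning to the smallest library, other tools and leaving out each replicate. A chi-square test of counts found that all 6 pairs of libraries differed beyond sampling noise, with chi-square per degree of freedom from 8.94 to 27.7, so none was treated as a second deposit of another. This test does not tell separate cultures from separate preparations of the same RNA. No batch was recorded in the labels or the file headers. The labels give 1 donor record, but Xist and Y-chromosome genes differed between replicates 1 and 2 and replicates 3 and 4, so that record does not stand for 1 animal. The spread between these 4 libraries, which the tests of spread measure, therefore does not separate technical differences from differences between animals, sex included.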

Results

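Gene expression was measured in 4 libraries of mouse cells labelled T-helper 17, with 29041979, 35018552, 48808978 and 45490373 counted fragments in replicates 1 to 4. The series holds no control group, so the comparisons were between gene programmes within these libraries and between the replicates. In all 4 libraries 9933 protein-coding genes reached 1 TPM, which is 45.6% of the 21764 measured, and single libraries held 10159 ± 33.4 (SD, n = 4). Values below are mean TPM ± SD over the 4 libraries unless another unit is given.

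The first question was how far the cells carried the Th17 programme. Genes that define mature Th17 cells were at low levels. Rora, which encodes an orphan nuclear receptor, was at 2.47 ± 0.372 TPM (n = 4). The cytokine genes Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496, plus strand) and Il17f were at 4.22 ± 1.53 and 9.83 ± 3.10 TPM. Both were measured in every library, and both were highest in replicate 1, at 6.36 and 14.4 TPM. Il21 was at 0.730 ± 0.352 TPM, the chemokine gene Ccl20 at 0.683 ± 0.24 TPM and its receptor gene Ccr6 at 0.229 ± 0.189 TPM. The receptor gene Il23r had 8 counts, Il22 had 8 and Il1r1 had 23 over all 4 libraries, which left each below 0.2 TPM on average.

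The transcription factor genes Stat3, Batf and Hif1a, which other CD4 T cells also use, were higher, at 117 ± 5.72, 85.4 ± 10.2 and 77.4 ± 1.85 TPM. The extracellular matrix protein gene Podnl1 was at 12.2 ± 1.16 and Irf4 at 9.98 ± 1.87 TPM. Maf was at 2.08 ± 0.226 and the aryl hydrocarbon receptor gene Ahr at 1.38 ± 0.0587 TPM. In all, 13 of the 24 Th17 list genes reached 1 TPM in every library, and the list's median was 1.38 TPM.

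**Figure D1:**
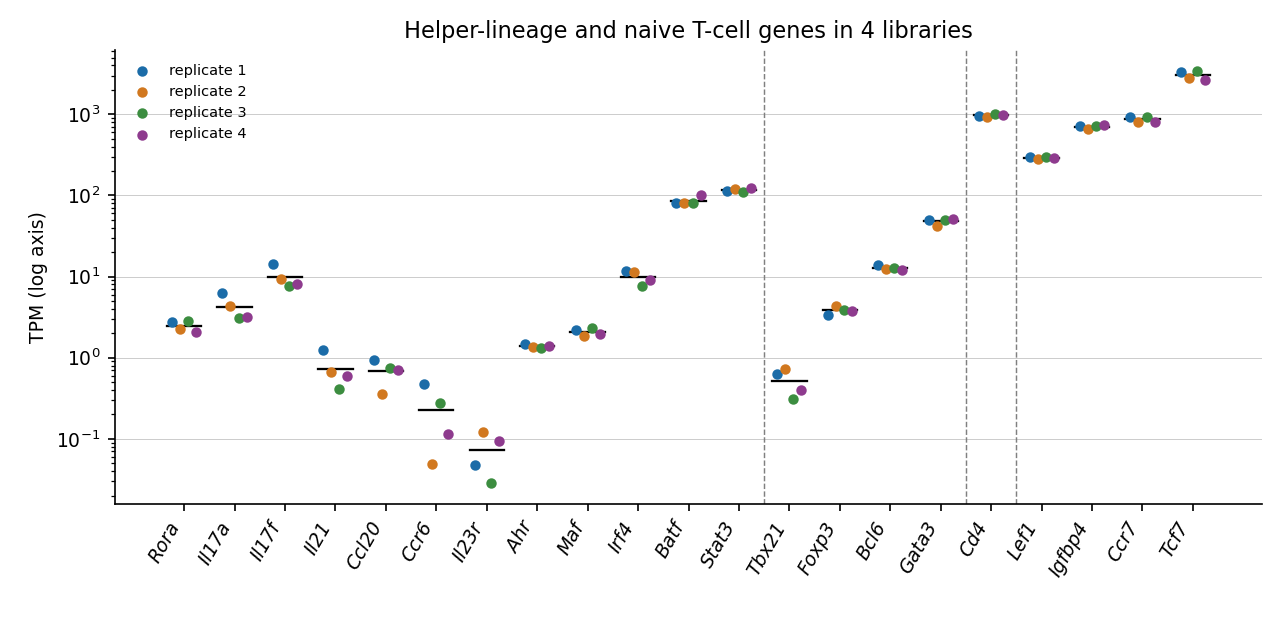
TPM on a log axis for helper-lineage and naive T-cell genes, with 1 point per library and a black line at the mean of the 4 libraries. From left to right, dashed lines separate Th17 list genes, regulators of other lineages, Cd4 and naive list genes. Il17a had a mean of 4.22 TPM and Tcf7 a mean of 3034 TPM.

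Genes of naive or resting T cells were among the most abundant transcripts. All 18 list genes exceeded 1 TPM in every library, and the list's median of 359 TPM lay at percentile 98.5 of nuclear protein-coding genes. Tcf7, which encodes the T-cell factor TCF1 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014, minus strand), was at 3034 ± 375 TPM (n = 4). The lymph node homing receptor gene Ccr7 was at 865 ± 71.4, the interleukin 7 receptor gene Il7r at 803 ± 185, Igfbp4 at 704 ± 31.2 and Lef1 at 292 ± 8.72 TPM. The Th17 list lay below the naive list by a mean log2(TPM + 1) difference of -6.24 ± 0.10 (SD, n = 4), in the same direction in 4 of 4 libraries (permutation p = 1e-05, the smallest these resamples can give, and adjusted p = 0.00014 over 14 comparisons).

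Genes common to T cells were abundant in every library. All 21 genes of that list exceeded 1 TPM, with Trac at 3069 ± 37.3, Trbc2 at 2932 ± 88.3, Trbc1 at 1909 ± 137 and the kinase gene Lck at 1351 ± 38.9 TPM. Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221, minus strand) was at 969 ± 34.2 TPM, whereas Cd8a was at 0.150 ± 0.0772 TPM with 23 counts. Their log2 ratio was 11.97 ± 0.41 and depends on the pseudocount, falling to 9.72 with a pseudocount of 1.

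Other helper lineages were mixed. The Th1 list had 8 of 20 genes at 1 TPM in every library, among them Il18r1 at 71.8 ± 5.47, Runx3 at 71.6 ± 9.76 and Stat4 at 60.9 ± 4.43 TPM, while the lineage regulator gene Tbx21 was at 0.518 ± 0.193 and Eomes at 3.07 ± 0.792 TPM. The Th2 list had 9 of 20, led by Stat6 at 292 ± 27.3 and Il4ra at 274 ± 9.50 TPM, with Crlf2 at 65.9 ± 3.89 and the regulator Gata3 at 48.1 ± 4.37 TPM. The regulatory T-cell list had 12 of 22, led by Izumo1r at 153 ± 2.27, Tnfrsf18 at 92.7 ± 9.61, Capg at 39.5 ± 3.39 and Tnfrsf4 at 30.4 ± 3.70 TPM, with its regulator Foxp3 at 3.82 ± 0.406 TPM. The follicular helper list had 14 of 18, led by Tcf7, Lef1, the costimulatory ligand gene Cd40lg at 257 ± 16.8 and Il6ra at 232 ± 6.77 TPM, with Bcl6 at 12.7 ± 0.822 TPM.

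The Th17 list was lower than the follicular helper list by -2.86 ± 0.06 on the mean log2(TPM + 1) scale (permutation adjusted p = 0.00854, 4 of 4 libraries). Without Tcf7 and Lef1, which the follicular helper list shares with the naive list, the difference was -2.19 (permutation adjusted p = 0.0268, an alternative added after the data were seen). Differences from the Th1, Th2 and regulatory lists were -0.24 ± 0.09, -0.06 ± 0.10 and -0.35 ± 0.06, and none passed the permutation test (adjusted p = 0.852, 0.933 and 0.747). The difference from the Th2 list was negative in 3 of 4 libraries, and with medians in place of means the differences from the Th1 and Th2 lists turned positive, at 0.59 and 0.90. With only list genes at 1 TPM or more in at least 1 library, the differences from the Th1, Th2 and regulatory lists were -1.08, -1.41 and -0.76. None passed the permutation test there (adjusted p = 0.641 for each).

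**Figure D2:**
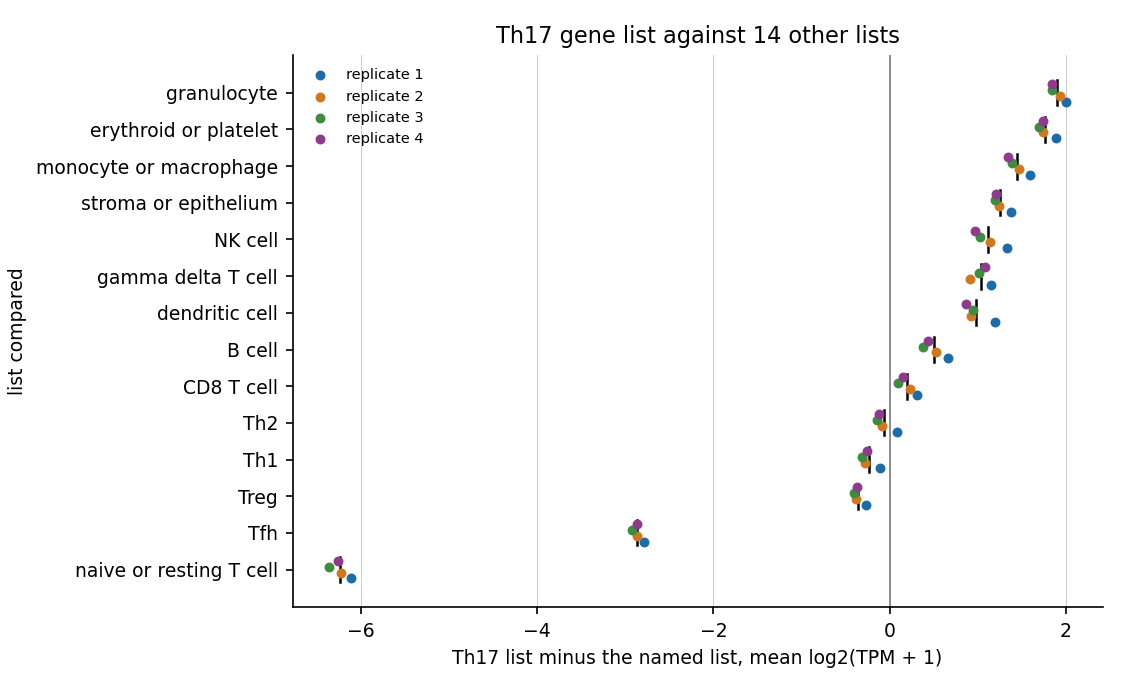
Difference in mean log2(TPM + 1) between the Th17 list and each of 14 other lists, with 1 point per library and a black line at the mean. The naive list lay farthest to the left, at -6.24, and the granulocyte list farthest to the right, at 1.91.

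Pairs of lineage genes were then compared within each library. Il17f exceeded Il17a by 1.22 ± 0.11 on the log2 scale (n = 4). The receptor pairs went against the Th17 partner, with Il23r over Il12rb2 at -1.50 ± 0.32 and Ccr6 over Cxcr3 at -1.67 ± 0.95. These receptor ratios rest on 8 counts of Il23r and 20 counts of Ccr6, and shrank to -0.38 and -0.59 with a pseudocount of 1. The direction was shared by 4 of 4 libraries in each of 7 pairs, the 6 given in the text and Il17a over Il4, and for each of these the exact sign-flip test gave the smallest p that 4 libraries allow (adjusted p = 0.136).

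The cytokine genes Ifng, Il4, Il5, Il10, Il13, Csf2 and Il9 were scarce. Ifng, the Th1 cytokine gene, had 0 counts in every library, which allows at most 0.163 to 0.278 TPM, so Il17a was at least 17.7-fold higher in each library against a floor of 3 counts per library. Il4 had 1 count over all 4 libraries, Il5 had 2, Il10 had 4, Il13 had 5, Csf2 had 10 and Il9 had 12. The log2 ratio of Il17a to Il10 was 4.61 ± 0.34 and depends on the pseudocount, falling to 2.24 with a pseudocount of 1. Tnf, a member of the Th1 list, was at 40.6 ± 3.07 and Il2 at 4.63 ± 1.49 TPM. Of the 33 genes listed for lymphocyte cytokines, 12 reached 1 TPM in every library. The highest were the lymphotoxin gene Ltb at 1109 ± 44.7, Il16 at 223 ± 5.74, Tgfb1 at 76.6 ± 4.57 and Tnfsf8 at 65.8 ± 5.76 TPM.

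Fixed lists of genes described as higher in pathogenic or in non-pathogenic Th17 cells were compared next. Because the Th17 programme was low in these libraries, the comparison does not place the cells in either state. The pathogenic signature had 5 of 17 genes at 1 TPM in every library, led by Lrmp at 75.5 ± 6.20, Stat4 and Icos at 42.3 ± 1.63, with Casp1 at 3.63 ± 0.494 TPM. The non-pathogenic signature had 9 of 15, led by Smad7 at 147 ± 8.05, Il6st at 146 ± 19.3, Tgfb1 and Ikzf3 at 64.5 ± 1.97 TPM. The pathogenic minus non-pathogenic difference was -1.43 ± 0.07 on the mean log2(TPM + 1) scale in 4 of 4 libraries and did not pass the permutation test (p = 0.127). The difference was -0.45 with only list genes at 1 TPM or more in at least 1 library (permutation p = 0.716). With log2(TPM + 0.1) it was -2.045 (permutation p = 0.103).

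Genes listed for the signals that drive Th17 differentiation partly reached 1 TPM. With no control group, this does not show whether these signals had acted. For the response to transforming growth factor beta, 13 of 20 genes reached 1 TPM in every library, led by the corepressor gene Ski at 227 ± 14.6, with Smad7 and Id2 at 88.0 ± 8.41 TPM. For interleukin 6 and STAT3 targets it was 17 of 18, led by the survival gene Mcl1 at 566 ± 54.2 and Il21r at 395 ± 32.6 TPM, then Junb and Il6ra. For the aryl hydrocarbon receptor it was 4 of 12, namely Nfe2l2 at 94.7 ± 0.767, Arnt at 45.6 ± 1.91, Tiparp at 23.8 ± 1.26 and Ahr, the receptor gene itself. The medians of these lists were 10.7, 91.9 and 0.214 TPM, in the order given. Of 19 chemokine receptor genes 8 reached 1 TPM in every library, led by Ccr7 and Cxcr4 at 304 ± 106, far above Cxcr1 at 4.11 ± 1.07 and Ccr8 at 3.81 ± 0.717 TPM.

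Mitotic genes were low. The median of the 25 G2/M genes was 0.811 TPM, with 9 at 1 TPM in every library, led by Cenpa at 19.8 ± 1.94, Cdc20 at 6.73 ± 0.346, Kif23 at 6.11 ± 1.17 and Aurka at 3.99 ± 0.387 TPM. The G1/S list had a median of 10.1 TPM and 19 of 24 genes at that level, led by Pcna at 130 ± 4.33, Mcm4 at 89.5 ± 1.30, Mcm6 at 61.8 ± 3.07 and Mcm3 at 51.3 ± 2.54 TPM. Early activation genes reached 1 TPM in every library in 21 of 24 cases, among them Jund at 358 ± 35.1, the phosphatase gene Dusp2 at 340 ± 105, Junb at 295 ± 56.3 and Ier2 at 239 ± 14.04 TPM. Genes listed for co-inhibitory receptors, their ligands and exhaustion factors reached 1 TPM in 8 of 12 cases. The highest were Btla at 162 ± 5.10, Cd274 at 43.7 ± 3.32, Tox at 31.5 ± 3.30 and Cd200 at 16.2 ± 2.04 TPM.

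The oxidative phosphorylation list stood above the glycolysis list in median level. All 28 oxidative phosphorylation genes reached 1 TPM, with a median of 108 TPM. Atp5a1 was at 688 ± 25.8, Atp5b at 535 ± 15.7, Cox4i1 at 444 ± 19.2 and Atp5c1 at 277 ± 11.2 TPM. Of the 20 genes on the glycolysis list 19 reached 1 TPM, with a median of 51.0 TPM. Ldha was at 517 ± 37.1, Pkm at 389 ± 8.82, Aldoa at 314 ± 13.6 and the listed kinase gene Pdk1 at 228 ± 31.9 TPM. This difference was not tested. Hypoxia response genes reached 1 TPM in 14 of 18 cases, led by Ddit4 at 723 ± 126, Bnip3l at 104 ± 5.24, Egln1 at 83.4 ± 5.24 and Kdm3a at 75.5 ± 2.72 TPM. Unfolded protein response genes did in 17 of 20, led by Calr at 431 ± 31.7, Atf4 at 334 ± 22.0, Hsp90b1 at 276 ± 47.2 and Hspa5 at 248 ± 12.4 TPM. The most abundant nuclear protein-coding genes were Eef1a1 at 16812 ± 615, Rplp1 at 12268 ± 170, Rpl8 at 8638 ± 293, B2m at 7336 ± 405, Actb at 7285 ± 424, Tmsb4x at 6207 ± 310, Rps15 at 6174 ± 357, Rplp0 at 5894 ± 216, H2-K1 at 5283 ± 88.0 and Eef2 at 5220 ± 219 TPM. The 31 listed ribosomal protein genes had a median of 1687 TPM, and Rpl4 was at 4999 ± 164 TPM.

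Markers of other cell types were mostly near the detection limit, with a few exceptions. The Th17 list exceeded the granulocyte list by 1.91 ± 0.07, the erythroid or platelet list by 1.77 ± 0.08 and the monocyte or macrophage list by 1.45 ± 0.11 on the mean log2(TPM + 1) scale, each in 4 of 4 libraries (permutation adjusted p = 0.0056, 0.0104 and 0.0215). The last call ended when genes under 1 TPM in all libraries were left out or medians were used, and the erythroid call ended with medians. It exceeded the lists for stroma or epithelium by 1.26 ± 0.09, NK cells by 1.12 ± 0.16, gamma delta T cells by 1.04 ± 0.10, dendritic cells by 0.98 ± 0.15, B cells by 0.50 ± 0.12 and CD8 T cells by 0.20 ± 0.10, and these did not pass the permutation test (adjusted p = 0.132, 0.174, 0.237, 0.237, 0.734 and 0.852). With genes under 1 TPM in all libraries left out, the Th17 list lay below the B-cell and stroma lists, at -0.79 and -1.57.

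Single genes of these lists were high. Ighm, the immunoglobulin mu heavy chain gene (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730, minus strand), was at 997 ± 24.2 TPM (n = 4), and H2-Ob at 77.4 ± 8.39 TPM, while 3 of the 16 B-cell genes reached 1 TPM in every library. Prf1, for the cytotoxic protein perforin, and Cd8b1, for the CD8 beta chain, were at 65.1 ± 7.28 and 42.9 ± 2.88 TPM, with 5 of 12 CD8 T-cell genes at 1 TPM. The NK list had 2 of 14, Klrd1 at 44.6 ± 4.86 and Eomes. The gamma delta list had 2 of 11, Sox4 at 12.6 ± 1.04 and Trdc at 9.37 ± 1.12 TPM. The myeloid list had 3 of 18, led by Cd68 at 11.1 ± 2.81 and Fcgr3 at 4.603 ± 1.04 TPM, and the dendritic list 2 of 15, Bst2, an interferon-stimulated gene, at 165 ± 23.5 and Cd74 at 7.79 ± 1.64 TPM. The adhesion gene Pecam1 at 160 ± 17.0 and Epcam at 2.35 ± 0.455 TPM were the 2 of 16 stroma or epithelium genes. Itga2b at 3.30 ± 0.383 TPM was the 1 of 14 from the erythroid or platelet list, in which Klf1 had 13 counts. Of 15 granulocyte genes 0 reached that level, with Csf3r at 11 counts and S100a9 at 5.

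The second question was how the 4 replicates differed. The biological coefficient of variation was 9.80% with a jackknife standard error of 1.85%. Of 12464 genes, 24 varied between libraries more than the trend for their abundance by edgeR's quasi-likelihood dispersion test, and 16 of these were highest in replicate 4. Leaving out replicate 2, 3 or 4 gave 13, 7 or 86 genes, of which 12, 7 and 17 were among the 24, so the count depends on single libraries. It was 6 among nuclear protein-coding genes alone, 10 with a mean CPM of 5 or more, 5 with a fit that was not robust, 349 without a filter, and 108 as DESeq2 dispersion outliers.

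Of the 30 lists tested for spread, the heat shock response had the largest SD over libraries, and its mean was highest in replicate 4. The list's mean log2 deviation from the 4-library mean was 0.71 in replicate 4, -0.51 in replicate 1, -0.03 in replicate 2 and -0.17 in replicate 3, and 12 of the 13 genes past the filter had their highest TPM in replicate 4. Hsph1 (ENSMUSG00000029657, chromosome 5, 149614287 to 149636376, minus strand) was at 26.0, 65.4, 33.0 and 195 TPM in replicates 1 to 4 (edgeR adjusted p = 0.000273). Hsp90aa1 was at 131, 170, 142 and 351 TPM (edgeR adjusted p = 0.0112), and Dnaja1 at 41.9, 69.0, 49.6 and 119 TPM (edgeR adjusted p = 0.0113). Hspa8 at 601 to 1490, Dnajb1 at 122 to 305, Chordc1 at 43.9 to 102 and Hsp90ab1 at 1557 to 3162 TPM were also called. The SD of the list over libraries was 0.516, against a median of 0.0262 for random lists (permutation p = 0.0001, the smallest possible, adjusted p = 0.0015), and 0.247 without replicate 4 (permutation adjusted p = 0.027). Of the 13 genes 8 were called over all genes tested and 13 adjusted over the list alone (Fisher's exact adjusted p = 1.96e-18 for enrichment), and with a mean CPM of 5 or more 3 of the 13 were called over all genes.

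Other called genes included cochaperones outside the fixed lists. Stip1 was at 143, 227, 166 and 457 TPM (edgeR adjusted p = 0.00719), Fkbp4 at 122 to 272 TPM and Ahsa2 at 21.6 to 55.5 TPM, with the highest value of each in replicate 4. Ccdc117 was also highest there, at 116 TPM, and Zc3h6 was lowest there, at 8.93 TPM against 16.4 to 29.1 TPM in the others. Eps8l1, an actin regulator gene, was at 2.96 TPM in replicate 1 and at 21.5 to 35.2 TPM in the others (edgeR adjusted p = 0.00165).

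Interferon-stimulated genes had their lowest mean in replicate 3. The 28 genes had a mean log2 deviation of -0.45 in replicate 3, 0.12 in replicate 1, 0.28 in replicate 2 and 0.05 in replicate 4, and 26 of them had their lowest TPM in replicate 3. Oas2 was at 61.4, 78.1, 30.3 and 61.9 TPM (edgeR adjusted p = 0.0396) and Ifit1 at 61.3, 73.7, 27.0 and 48.1 TPM (edgeR adjusted p = 0.0482). Oas3 at 12.4 to 29.1 TPM and Rsad2 at 2.29 to 11.98 TPM were not called (edgeR adjusted p = 0.0601 and 0.0596). More abundant members were Ifi203 at 187 ± 22.4, Zbp1 at 149 ± 21.6 and Bst2. The SD over libraries was 0.316 (permutation p = 0.0001, the smallest possible, adjusted p = 0.0015), and the call ended without replicate 3, at 0.117 (permutation adjusted p = 0.057). Of the 28 genes 2 were called over all genes and 19 adjusted over the list alone (Fisher's exact adjusted p = 0.0195 for enrichment). The enrichment ended with a mean CPM of 5 or more, where 0 of 26 were called.

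**Figure D3:**
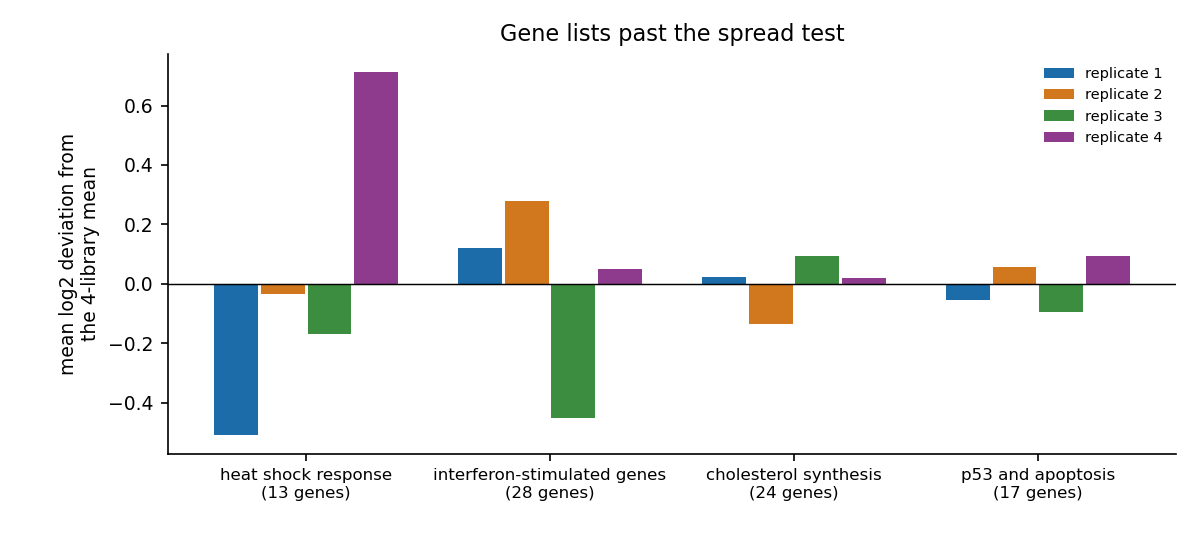
Mean log2 deviation from the 4-library mean, as bars starting at 0, for the 4 gene lists past the spread test, with 1 bar per replicate. Heat shock genes reached 0.71 in replicate 4 and interferon-stimulated genes -0.45 in replicate 3.

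The p53 and apoptosis list and the cholesterol synthesis list passed the spread test narrowly, with an SD of 0.0894 and 0.0955 (permutation adjusted p = 0.048 for both), and each call ended under some alternatives. The SD of the cholesterol list was 0.0421 without replicate 2 (permutation adjusted p = 0.499), and that of the p53 list 0.0674 without replicate 3 (permutation adjusted p = 0.13). In the p53 list, Bbc3, which encodes the death factor PUMA, was at 30.0, 86.6, 30.8 and 59.6 TPM (edgeR adjusted p = 0.0323), and it was the 1 called gene of 17, also when adjusted over the list alone. Bcl2l11 at 30.7 to 43.1, Aen at 19.3 to 23.5 and Pmaip1 at 0.558 to 1.96 TPM were not called, and the most abundant members were Trp53inp1 at 174 ± 9.99, Ccng1 at 164 ± 8.01, Bax at 131 ± 8.65 and Sesn1 at 126 ± 7.45 TPM. Of 24 cholesterol synthesis genes 0 were called by edgeR over all genes or adjusted over the list alone, and 2 had an unadjusted p below 0.05. The list's mean was lowest in replicate 2, at -0.13, with Sqle at 9.82, Msmo1 at 11.8 and Fdft1 at 18.5 TPM there, while Srebf2 was at 239 ± 7.95, Hmgcs1 at 59.6 ± 4.18 and Ebp at 47.1 ± 1.32 TPM.

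The other 26 lists did not pass the spread test, among them the Th17 list, with a mean log2 deviation of 0.13 in replicate 1 and an SD of 0.090 (permutation adjusted p = 0.123), and the naive list, with an SD of 0.0522 (permutation adjusted p = 0.206). Adjusted over the list alone, 8 of 23 activation genes, 4 of 18 naive genes, 4 of 17 STAT3 targets, 1 of 15 hypoxia genes and 1 of 9 chemokine receptor genes were called excess variable. The last of these, Cxcr4, was also called over all genes tested, at 209, 404, 216 and 388 TPM (edgeR adjusted p = 0.0368). Over all genes tested, 0 of the activation, naive, STAT3 and hypoxia genes were called. Adjustment within a list does not correct for the number of lists. Of all 12464 genes tested, 665 had an unadjusted edgeR p below 0.05. Il7r was at 632, 971, 654 and 956 TPM and was not called over all genes (edgeR adjusted p = 0.19). Without replicate 4 the number of lists past the test was 12, and without replicate 2 or 3 it was 2.

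Sex chromosome genes separated the libraries. Xist, the RNA of the inactive X chromosome (ENSMUSG00000086503, chromosome X, 103460375 to 103483217, minus strand), was at 224 and 215 TPM in replicates 1 and 2, and at 0.294 and 0.445 TPM in replicates 3 and 4 (edgeR adjusted p = 1.41e-06). Ddx3y, a Y-chromosome helicase gene (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629, minus strand), was at 0.439 and 0.658 TPM in replicates 1 and 2, and at 97.2 and 139 TPM in replicates 3 and 4 (edgeR adjusted p = 3.54e-06). Eif2s3y at 96.9 and 81.9 TPM, Kdm5d at 23.9 and 25.5 TPM and Uty at 15.01 and 16.03 TPM in replicates 3 and 4 stayed below 0.3 TPM in replicates 1 and 2. The 1 donor record in the labels therefore does not stand for 1 animal, and the spread between libraries includes whatever differed between the animals. Eif2s3y, Kdm5d and Uty did not reach the count minimum in every library. When the minimum was required in at least 1 library, an alternative added after the data were seen, 52 genes were called, 5 of them on chromosome Y.

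**Figure D4:**
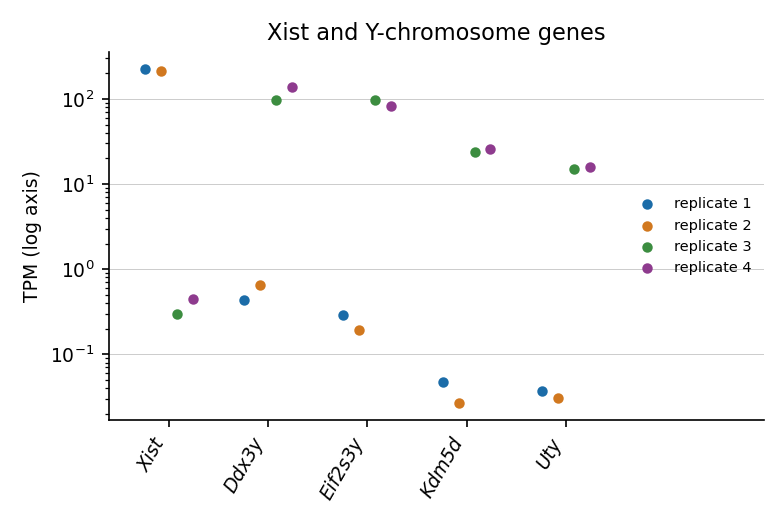
TPM on a log axis for Xist and 4 genes of the Y chromosome, with 1 point per library. Xist was above 200 TPM in replicates 1 and 2, and the Y-chromosome genes were between 15.01 and 139 TPM in replicates 3 and 4.

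Counts were then divided by class of gene. Protein-coding genes took 98.1% ± 0.131 of counts (SD, n = 4), mitochondrially encoded genes 2.00% ± 0.157, cytoplasmic ribosomal protein genes 6.16% ± 0.251, and the 10 highest genes 5.32% ± 0.181. Long intergenic RNA genes, Xist among them, took 0.671% and 0.621% in replicates 1 and 2 and 0.491% and 0.470% in replicates 3 and 4. Listed genes for transcripts without a poly(A) tail took small shares of counts, and so did mitochondrial ribosomal RNA. Fragments shared between near-identical copies were not counted, which lowers the shares of such gene families by an unknown amount. Replication-dependent histone genes took 0.00242% ± 0.000479 and the listed small RNA genes 0.000801% ± 0.000135, and mitochondrial ribosomal RNA took 0.0284% ± 0.00364. The highest histone genes were Hist1h1c at 22.8 ± 6.33, Hist1h4d at 15.5 ± 3.12, Hist1h4c at 12.7 ± 0.949 and Hist2h2ac at 9.08 ± 1.35 TPM, and the highest small RNA genes were Rn7sk at 49.9 ± 14.8, Snora73b at 12.4 ± 0.612, Scarna2 at 7.66 ± 0.0995 and Rnu11 at 7.44 ± 2.40 TPM.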

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

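Each of 222 values per library was checked for 1 library far from the other 3, as a large gap relative to the range, and 14 were found, where chance gives about 11.1. Replicate 4 stood apart, highest, for Actb at 7921 TPM, Batf at 101 TPM, Hsp90b1 at 346 TPM, Prf1 at 76.0 TPM, Runx3 at 86.2 TPM and Tgfb1 at 83.4 TPM, and lowest for Lrmp at 66.3 TPM. Replicate 2 stood apart for Casp1, lowest at 2.89 TPM, and, on few counts, for Klf1 at 0.461 TPM and Il4 at 0.0821 TPM. Replicate 3 stood apart for Cenpa, lowest at 16.9 TPM, and for Il5 at 0.0915 TPM, on 2 counts. Replicate 1 stood apart for Hist2h2ac at 11.1 TPM and for the non-pathogenic Th17 signature, whose mean log2 deviation was 0.15 there. The tests of explanations below were chosen after the pattern was seen, and their values had also been seen when they were chosen. For depth, 2 other tests, on thinned counts and on replicate 3 alone, were tried first and left out because their outcome was fixed beforehand.

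Heat shock genes were highest in replicate 4, with a mean log2 deviation of 0.71. Unequal depth was not decided by the test run. Counts were scaled to depth before the random lists were drawn, and the same random lists had given the heat shock call. These lists, matched on expression decile, had a median SD over libraries of 0.0262 against 0.516 for the heat shock list. The values show that the heat shock list differed more between libraries than lists of genes of similar abundance. A bias of GC content or gene length is argued against as the whole source, because the SD over libraries was 0.52 after a linear trend on both was removed in each library, with GC values for 13 of 13 genes. The unfolded protein response list had a mean log2 deviation of 0.0226 in replicate 4 and did not pass the spread test. Its SD over libraries was 0.0307, against a median of 0.0266 for random lists (permutation adjusted p = 0.5). A stress response that includes the endoplasmic reticulum stays open, because the list's members went both ways. In replicate 4, 10 of 17 were above their mean and 7 below. Hsp90b1 was at 346 TPM there against 246 to 262 in the others, and Hspa5 at 266 TPM against 238 to 245. Atf4 was lowest there, at 316 TPM against 319 to 364 in the others. Differences in handling, temperature or the animals, sex included, stay open and were not tested, because the labels put all 4 libraries in 1 group and give no sex (replicates 1 and 2, which expressed Xist, were at -0.51 and -0.03, and replicates 3 and 4, which expressed Y-chromosome genes, at -0.17 and 0.71).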

How the results depend on the processing

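Alternatives that needed posterior mean TPM or counts were not run, because the deposited values are whole counts. No paired analysis was possible because the series has 1 group. Added after the data were seen were the Tfh list without naive genes, the GC and length trend, the genes without chromosomes X and Y, and the count minimum met in at least 1 library. The number of genes detected (8695 to 10344) and the biological coefficient of variation (0.0826 to 0.112) stayed within their limits in the alternatives run, and the Th17 minus naive and Th17 minus Tfh calls and the direction of the signature difference held in each. The causes of the changes below were not tested, except where the alternative itself shows one.

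With medians, Th17 minus Th1 was 0.59 and Th17 minus Th2 0.90, both reversed, and the calls against the monocyte list (1.15) and the erythroid list (1.25) were lost (permutation adjusted p = 0.0796 for both). With log2(TPM + 0.1), Th17 minus Th2 was 0.60, reversed, and Th17 minus stroma became a call at 2.62 (permutation adjusted p = 0.0186). Without length correction Th17 minus Th2 was 0.0356, reversed. With only genes at 1 TPM or more in at least 1 library, Th17 minus B cell was -0.79, Th17 minus stroma -1.57 and Th17 minus monocyte 0.49, which lost its call. That filter left too few granulocyte and erythroid genes for a value.

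With log2(TPM + 1), the log2 ratios shrank to 2.24 for Il17a/Il10, 1.06 for Il17f/Il17a, -0.38 for Il23r/Il12rb2, -0.59 for Ccr6/Cxcr3 and 9.72 for Cd4/Cd8a. This follows from the larger pseudocount beside low values. Without length correction they were 3.53 for Il17a/Il10 and 1.94 for Il17f/Il17a.

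Excess variable genes numbered 349 without a filter (24 shared with the main 24), 10 with a mean CPM of 5 or more (7 shared), 6 for nuclear protein-coding genes (6 shared), 5 without the robust fit (5 shared), 108 as DESeq2 dispersion outliers (24 shared), 52 with the minimum met in at least 1 library (24 shared), and 7 to 86 without 1 replicate. They numbered 24 with DESeq2 size factors, 21 with total counts only and 19 without chromosomes X and Y. Enriched lists numbered 2 in the main analysis. They numbered 3 with an adjusted p below 0.1, with the activation list added (Fisher's exact adjusted p = 0.0363). They numbered 2 with a mean CPM of 5 or more, but only heat shock was shared, with 3 of 13 genes called against 8 in the main analysis (Fisher's exact adjusted p = 3.05e-06). There the interferon call ended, with 0 of 26 genes called, and the sex chromosome list, with 5 of 5 called, entered (Fisher's exact adjusted p = 1.04e-14). Lists past the spread test numbered 2 to 12 without 1 replicate. The heat shock call held in all 9 alternatives run, the interferon call in 8 of 9, the p53 call in 6 of 9 and the cholesterol call in 4 of 9. Count shares moved when given as TPM shares, for example to 14.4% for ribosomal protein genes and 5.17% for mitochondrially encoded genes. Depth limits genes under 3 counts in a library, such as Ifng and Il4.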

Other observations

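The tests of explanations in this part were chosen after the patterns were seen, and the prediction on immunoglobulin variable genes was written before its result was seen. Some genes were called excess variable only when the count minimum was required in at least 1 library, and those named here were chosen after their values were seen. Cirbp, which encodes a cold-inducible RNA-binding protein, was at 204, 137, 185 and 95.01 TPM in replicates 1 to 4, with its lowest value in replicate 4 (edgeR adjusted p = 0.0201, against 0.0506 with the minimum in all 4 libraries). The chaperonin gene Hspd1, already counted in the heat shock list, was at 127, 155, 134 and 237 TPM (edgeR adjusted p = 0.0275, against 0.0601). The cochaperone gene St13 was at 82.1, 109, 89.7 and 162 TPM (edgeR adjusted p = 0.0223, against 0.0545). Both had their highest value in replicate 4. Kdm6a, a histone demethylase gene on chromosome X related to Uty, was at 66.5 and 66.9 TPM in replicates 1 and 2 and at 38.5 and 39.5 TPM in replicates 3 and 4 (edgeR adjusted p = 0.0295, against 0.0667). Cpt1a, for an enzyme of fatty acid oxidation, was at 107, 110, 51.4 and 92.8 TPM (edgeR adjusted p = 0.022, against 0.0523).

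The libraries labelled Th17 had a low Th17 programme beside a high naive programme. Too little depth is argued against, because Il17a at 1 TPM would have 9.75 counts in the smallest library. A candidate explanation is that the cells were taken at hour 0 of a differentiation time course, as the hour tag in the file headers reads, and the Th17 minus naive difference of -6.24 is in the direction this needs. This test was chosen after the values were seen, whereas the hour tag was not drawn from them. A label that names the intended fate of a culture would go with hour 0. A sample of naive cells from elsewhere predicts the same difference. A minority of differentiated cells may account for the Il17a and Il17f transcripts, with at least 48 counts of Il17a in each library, but a low level in every cell predicts the same, and these cannot be told apart in counts from bulk RNA.

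Ighm lay far above Igkc and 4 other B-cell transcripts, and Cd8b1 far above Cd8a. B cells among the sampled cells are argued against as the source of Ighm, since it was at least 100.2-fold above each of Igkc, Cd79a, Cd79b, Cd74 and Ms4a1 in every library, and Igkc was at 1.48 ± 0.861 TPM (SD, n = 4), though these 5 were chosen after their values were seen and the margin does not hold for H2-Ob, at 67.1 to 86.9 TPM. CD8 T cells are argued against as the source of Cd8b1, which was at least 164-fold above Cd8a in every library. A candidate explanation is that Ighm was transcribed without a variable region, since the 113 immunoglobulin heavy variable genes together had at most 0.0252% of the Ighm counts in a library. Fragments shared between variable genes were not counted, which lowers that share by an unknown amount, and counts per gene do not show which exons of Ighm were covered.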
